A study of Homo sapiens with 4 samples.

How the data were processed

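Total RNA from U87 cells in medium with serum was labelled with biotin and measured on Affymetrix whole-transcript arrays, with 4 arrays in all and 1 per condition. The labels state that RNA of the cultures was extracted at the same time with 1 kit. The authors deposited log2 expression values; RMA, which corrects background, normalizes by quantiles and summarizes probes, is named in the submitters' processing notes with affy 1.36.1 and R 2.15.1. The values of the arrays have nearly equal distributions. Features are named by Entrez gene number, 1 per gene, so no averaging over features was needed. Of 23786 features, 22458 had 1 symbol in the platform's gene table, none had several and 1328 were unnamed here. Scanner files and detection calls were not used here, so no feature can be called absent, and differences between low values are compressed toward 0.

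Groups were taken from the labels. For the 21-day pair the treatment protocol gives 1 culture name to both arms and the array labels say only sensitive and resistant. The resistant array was taken as the culture in crizotinib and the sensitive array as its drug-free control, from the design text and the protocol's wording, and the sign of every chronic difference rests on this reading. Each treated array was set against its own control: 2 µM crizotinib for 24 hours minus vehicle, and 1 µM for 21 days minus the 21-day control. The arrays without drug were compared as a yardstick that holds culture, passage and array differences together. With 1 array per condition there is no residual degree of freedom within a pair, so genes were counted by size, at least 2-fold with the higher array at or above the median of all values (4.96), and no p-value was computed for these differences. The overlap of the comparisons was set against that of independent lists, and their differences were correlated across genes.

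There were 39 gene lists, fixed before the data were examined along with the rules, the main fits and most alternatives; the report gives the median of each. A list's median was computed with its 95% binomial interval over members, printed for lists outside the central 95% of random lists in the treated comparisons, and its percentile among 10000 random lists of the same size drawn from 20 bins of mean level. Both describe these arrays and are not tests of the conditions. Members without a feature were not analysed here. A further 3 lists were written later for the tests in the closing section: fibroblast markers, keratinocyte markers and secreted factors of arrested cells. The pattern these lists address was renamed after their results were seen, with their predictions unchanged. A first test of a low vehicle array asked whether the 24-hour crizotinib array lay above both untreated arrays; it was replaced because the untreated arrays differ in that list.

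Genes named in the text follow a rule also fixed beforehand: the 12 highest and 12 lowest differences of each comparison, the 8 highest and 8 lowest by the smaller change in both, the 6 highest and 6 lowest of chronic minus acute among genes passing the level filter in both, the 8 smallest p of each limma fit, the list members at least 2-fold changed or among the 2 highest or 2 lowest of their list, and MET, HGF, ALK, ROS1, PPARGC1A and CREB1. Noncoding families and provisional names were left out of the rule, which gave 404 genes. Genes named for the arrays without drug were chosen by their difference after values were seen.

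Model fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05) on 11891 features whose mean passed the level filter. Of the fits, the first took the untreated arrays as one control group for both treated arrays, and the second took crizotinib over both pairs with the pair as a covariate. Each has 1 residual degree of freedom, and lone treated arrays are assumed to vary like the rest. The p-values measure only the spread between these cultures. For each list the members past the threshold were counted over all genes and with adjustment over the list alone, and the report prints these counts for many of the lists.

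The rules were tested on simulated data. For single genes, all 4 simulated arrays had independent noise around the same means, and each planted change was equal in both treated arrays. The measured pairs differ in dose, time and culture, so the recoveries hold only for the simulated setting. With noise of SD 0.289 per array and 50 planted genes per size among 11891, the chronic limma fit recovered 32% of changes of 1 on the log2 scale and 98% of changes of 2, the acute fit 16% and 96%, and the fit over both pairs 38% and 100%. The size rule recovered 40% and 100% and called 188 unchanged genes. That count also holds only for the simulated noise. Between the measured arrays without drug, 379 genes were at least 2-fold apart among 12397 features past the level filter. Random lists of 35 genes fell outside the central 95% in 4 of 100 draws without a shift, 74 with a shift of 0.2 and 100 with 0.5. For 12 genes the counts were 5, 28 and 94. These lists held randomly picked genes with independent noise, so they do not show how often lists of related genes fall outside without an effect. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

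Alternatives were no level filter, a filter at the 75th percentile of values (7.00), quantile normalization again, centring on the median difference, a 1.5-fold threshold, the mean of the untreated arrays as control, eBayes with trend and robust settings, no pair term, lists limited to members past the filter, and random lists not matched on level. The untreated array of the other experiment as control, and quantile normalization for the lists, were added after the data were seen.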

Results

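Gene expression was measured in U87 cells, an established human glioblastoma line, with and without crizotinib, an inhibitor of the receptor tyrosine kinases MET, ALK and ROS1. There were 4 arrays, 1 per condition: vehicle for 24 hours, 2 µM crizotinib for 24 hours, a control culture kept without drug for 21 days, and cells kept in 1 µM crizotinib for 21 days. The labels call the last pair crizotinib-sensitive and crizotinib-resistant, read here as the control and the drug culture. The first pair asks what acute exposure does to expression, and the second pair asks what chronic exposure does. Values are log2 expression per gene, for 23786 features of which 22458 carried 1 gene symbol. Array medians lay between 4.92 and 4.98, and values ran from 1.07 to 12.56, so the arrays were on a common scale. No condition was repeated, so no single difference between a treated array and its control has a replicate check, and the number of arrays limits the precision of every value. Genes are therefore described by size: a difference of at least 2-fold, with the higher array at or above the median of all values, 4.96. Unless limma is named, higher and lower describe the arrays that were measured.

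In the acute comparison, genes of cholesterol and fatty acid synthesis were higher and genes of DNA replication, histones and growth factor signalling were lower in the crizotinib array. Of 12468 features that passed the level filter, 359 were at least 2-fold higher and 265 at least 2-fold lower. With noncoding RNAs left out, the highest differences belonged to FABP3 (Entrez gene 2170), a fatty acid binding protein, at 4.47 on the log2 scale, PPARGC1A (Entrez gene 10891), the coactivator PGC-1alpha that drives mitochondrial biogenesis, at 2.88, and HMGCS1 (Entrez gene 3157), the cytosolic HMG-CoA synthase, at 2.83. The lowest belonged to the histone genes H2AC4 at -2.45 and H1-1 at -2.34, to PLAU, the protease urokinase, at -2.31, to the open reading frame C10orf55 at -2.29 and to the histone gene H1-5 at -2.20.

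Cholesterol synthesis was the list with the highest acute median. Of its 19 measured members, 15 were at least 2-fold higher and 18 were above 0, and the median difference was 1.45 (95% binomial interval of the median 1.00 to 1.80), at percentile 100 among 10000 random lists of the same size and level. Besides HMGCS1, the differences were 2.00 for IDI1, the isopentenyl diphosphate isomerase, 2.09 for TM7SF2, a sterol reductase, 1.70 for SQLE, the squalene epoxidase, and 1.64 for MSMO1, a sterol oxidase. PMVK, the phosphomevalonate kinase, was the 1 member that was lower, at -0.80. Fatty acid synthesis had a median of 0.59 (0.01 to 1.68, percentile 100), with 5 of 14 members at least 2-fold higher. These included ACSS2, which makes acetyl-CoA from acetate, at 2.00, the desaturase FADS2 at 1.74, fatty acid synthase FASN at 1.68 and the stearoyl-CoA desaturase SCD at 1.35. Both lists also differed between the arrays without drug: cholesterol synthesis was lower in the 21-day control than in the 24-hour vehicle array, with a median of -0.83, and fatty acid synthesis at -0.36.

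All 35 measured genes of DNA replication and the G1/S transition were lower after 24 hours of crizotinib, 25 of them at least 2-fold, with a median of -1.20 (-1.38 to -1.05, percentile 0.0). GINS2, a subunit of the replicative helicase, differed by -2.12, the replication initiation factor MCM10 by -1.85, DTL, a substrate receptor for licensing control, by -1.68 and the ribonucleotide reductase subunit RRM2 by -1.49. All 33 genes of G2/M and mitosis were also lower, with a median of -0.85 (-0.94 to -0.60, percentile 0.0) and 10 at least 2-fold. Examples were UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, at -1.44, Aurora kinase B (AURKB) at -1.34 and cyclin A2 (CCNA2) at -1.22. Histone genes had a median of -0.73 (-1.95 to -0.21, percentile 0.0), with 4 of 14 at least 2-fold lower. Histone genes are near-identical copies whose probes can share signal, so single members are uncertain.

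Targets that report on growth factor signalling were lower as well. The ERK feedback list had a median of -0.48 (-0.95 to -0.22, percentile 0.0), with 5 of 20 members at least 2-fold lower: the AP-1 subunit FOSL1 at -1.88, the transcription factor MYC at -1.47, cyclin D1 (CCND1) at -1.19, the ERK phosphatase DUSP6 at -1.16 and the transcription factor ETV4 at -1.11. YAP and TEAD targets had a median of -0.69 (-0.95 to -0.10, percentile 0.0, 2 of 16 at least 2-fold lower), among them GADD45B at -1.19 and the RhoGAP DLC1 at -1.11. Growth factor ligands had a median of -0.27 (-0.68 to -0.04, percentile 0.39), with the EGF receptor ligand HBEGF at -1.49. TGF-beta targets had a median of -0.28 (-0.70 to 0.13, percentile 1.01), and their members parted: the HLH inhibitor ID1 was at -1.37 and its relative ID3 at 1.19. FOXO targets were higher, with a median of 0.72 (0.07 to 0.96, percentile 100) and 11 of 17 at least 1.5-fold higher. They included the ubiquitin ligase subunit FBXO32 at 2.40, the atypical cyclin CCNG2 at 2.17 and the sestrin SESN3 at 1.92.

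Lysosome and TFEB target genes had an acute median of 0.34 (0.21 to 0.57, percentile 100), with the V-ATPase subunit ATP6V0D2 at 2.48 and the glycoprotein GPNMB at 2.11, and autophagy genes a median of 0.32 (0.01 to 0.43, percentile 99.89), with WIPI1 at 1.09. NRF2 targets had a median of 0.23 (0.09 to 0.57, percentile 98.52), led by the heme oxygenase HMOX1 at 1.58. Fatty acid oxidation genes had a median of 0.24 with an interval that reached 0 (0.00 to 0.47, percentile 98.93), and metallothioneins one of 0.44 with an interval that included 0 (-0.42 to 0.79, percentile 99.95), and limma called no member of either list over the list alone. The metallothionein list was also higher between the untreated arrays, at 0.29. Lower were the mitochondrial ribosomal proteins (-0.31, -0.47 to -0.13, percentile 0.01) and cytosolic ribosomal proteins (-0.35, -0.45 to -0.30, percentile 0.0). Serine and one-carbon synthesis had a median of -0.46 (-0.65 to 0.08, percentile 0.08), with the serine pathway enzyme PHGDH at -0.98. Regulators of mitochondrial biogenesis went both ways, with 7 members above and 8 below 0 and a median of -0.25 (-0.45 to 0.22, percentile 2.19). PPARGC1A was the 1 member of that list at least 2-fold changed, and the 35 measured genes of respiratory complex I had a median of 0.07 (percentile 84.08). Serine and one-carbon genes were higher in the 21-day control than in the 24-hour vehicle array, at 0.39.

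The remaining lists lay within the central 95% of random lists in the acute comparison. Their medians were 0.05 for respiratory complexes II to V, -0.02 for the tricarboxylic acid cycle, -0.16 for glycolysis, 0.03 for ATF4 and amino acid response genes, -0.11 for the unfolded protein response, -0.06 for heat shock genes, 0.06 for hypoxia targets and 0.12 for p53 targets. They were -0.12 for the BCL2 family, 0.06 for receptor tyrosine kinases, -0.16 for NF-kB cytokines and chemokines, 0.14 for interferon-stimulated genes, 0.01 for extracellular matrix, -0.08 for glioma stem and proneural genes, 0.00 for astrocyte and neuron differentiation and 0.08 for drug efflux and metabolism. Of 28 measured receptor genes, 2 were at least 2-fold higher, PDGFRB at 1.485 and DDR1 at 1.085, and 1 at least 2-fold lower, EPHA2 at -1.193. Marker lists of cells that the culture should not hold had medians of -0.10 (leukocyte), 0.07 (endothelial) and -0.18 (epithelial). Of the drug's targets, MET (Entrez gene 4233) differed by -0.29 from a level of 10.17, ROS1 by 0.39 and ALK by 0.07, the latter pair with at least 1 array below the level filter. The MET ligand HGF differed by -0.67, and CREB1, a transcription factor upstream of PPARGC1A, by 0.22.

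With the untreated arrays as one control group, limma tested 11891 features, and 1 gene passed an adjusted p of 0.05 in the acute comparison: FABP3 rose by 4.49 (SE 0.22, adjusted p = 0.0485, limma). At an unadjusted p of 0.05, 1935 features passed. Adjusted over the list alone, 17 of 19 cholesterol synthesis genes, 5 of 12 fatty acid synthesis genes and 5 of 13 FOXO targets were higher. On the same footing 32 of 34 DNA replication genes, 20 of 33 G2/M genes, 8 of 18 ERK feedback targets, 6 of 15 YAP and TEAD targets and 6 of 11 histones were lower, while none of these passed over all genes tested. NRF2 targets had 2 of 16 higher over the list alone, and lysosome, autophagy, serine and both ribosomal protein lists had none. The fit has 1 residual degree of freedom, from a pair of untreated cultures that differ in more than the array, and without the level filter 0 genes passed. Its control group includes the 21-day control, where the cholesterol and fatty acid synthesis lists were lower than in the vehicle array, at -0.83 and -0.36. Most of their members therefore rose further in the fit than against the vehicle array alone. Set against the 21-day control, the 24-hour crizotinib array gave 681 higher and 656 lower genes, and 269 of the 359 higher and 215 of the 265 lower genes were again at least 2-fold apart in the same direction.

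**Figure D1:**
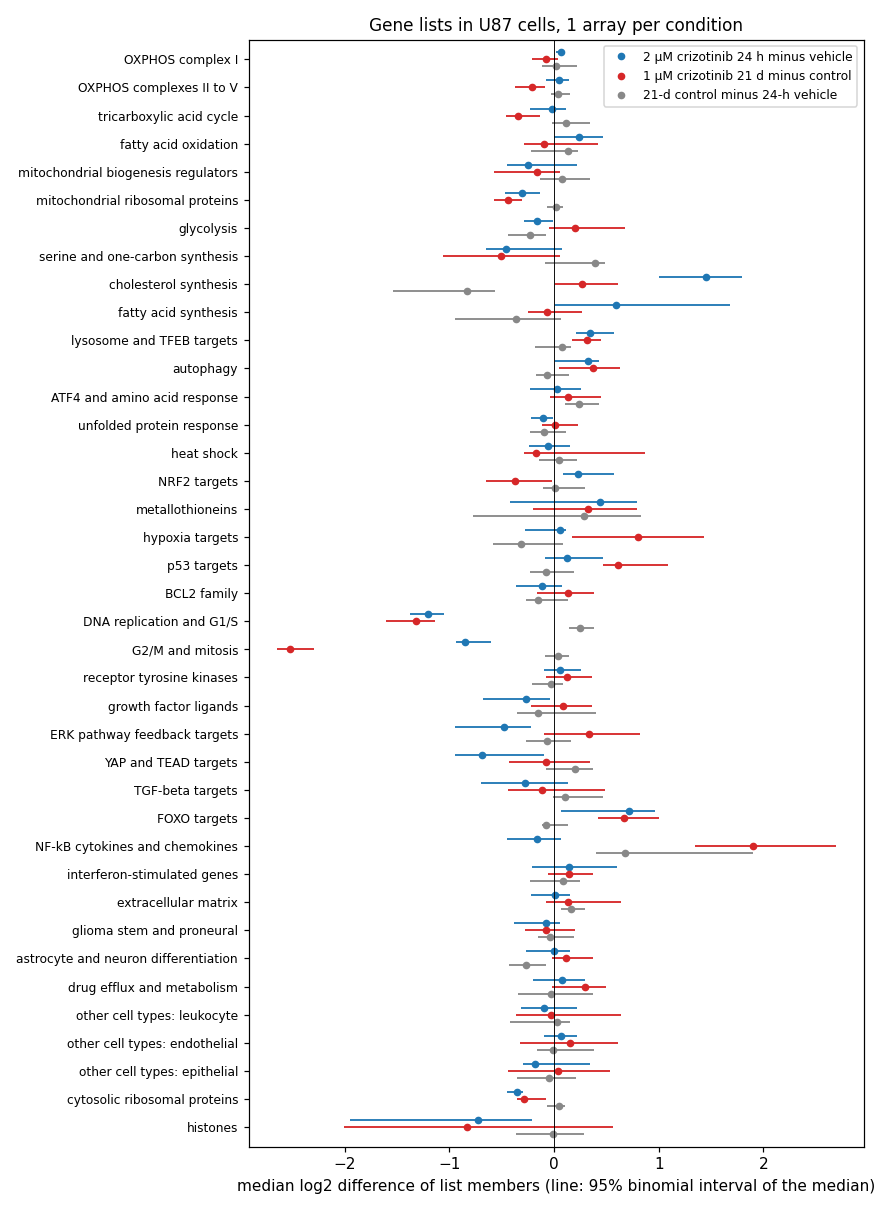
Median log2 difference of the members of each gene list (points), with its 95% binomial interval (lines), for 24 hours of 2 µM crizotinib, 21 days of 1 µM crizotinib and the pair of arrays without drug. Cholesterol synthesis lies at 1.45 in the acute and 0.27 in the chronic comparison, G2/M and mitosis at -0.85 and -2.52, and NF-kB cytokines and chemokines at -0.16 and 1.90.

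In the chronic comparison, cell division genes were lower and NF-kB cytokine and chemokine genes were higher in the cells kept in crizotinib. Of 12450 features that passed the filter, 494 were at least 2-fold higher and 508 at least 2-fold lower. The highest differences were those of the serpin SERPINB4 at 5.93, the proteoglycan decorin (DCN, Entrez gene 1634) at 5.01, the macrophage metalloelastase MMP12 at 4.66, the small heat shock protein CRYAB at 4.10, the matrix protease MMP7 at 3.94 and the IGF binding protein IGFBP1 at 3.69. The lowest were those of the histone genes H2BC14 at -4.30, H3C2 at -3.67, H3C11 at -3.63 and H1-5 at -3.60, the kinetochore gene SPC25 at -3.33, the cystine transporter SLC7A11 at -3.25, the histone gene H3C8 at -3.19 and Polo-like kinase 1 (PLK1, Entrez gene 5347) at -3.11.

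All 33 measured genes of G2/M and mitosis were at least 2-fold lower in the 21-day crizotinib array, with a median of -2.52 (-2.65 to -2.29, percentile 0.0). Besides PLK1, the spindle protein DLGAP5 differed by -3.09, the kinetochore protein NDC80 by -2.91, cyclin A2 (CCNA2) by -2.88, the proliferation marker MKI67 by -2.82 and topoisomerase TOP2A by -2.60. In limma, 31 of the 33 fell when adjusted over all genes and 33 of 33 when adjusted over the list alone. All 35 DNA replication genes were lower, 27 at least 2-fold, with a median of -1.32 (-1.61 to -1.14, percentile 0.0). MCM10 was at -2.76, the primase PRIM1 at -2.60 and cyclin E2 (CCNE2) at -2.16, and limma placed 5 of 34 past the threshold over all genes and 31 over the list alone. The same list was 0.25 higher in the 21-day control than in the 24-hour vehicle array. Histones had a median of -0.83 (-2.01 to 0.56, percentile 0.0) and moved both ways: 7 of 14 were at least 2-fold lower, while H2BC21 was at 2.52 and H2BC5 at 1.19. These are genes whose transcripts can be polyadenylated outside S phase.

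NF-kB cytokines and chemokines had the highest chronic median, 1.90 (1.35 to 2.69, percentile 100), and 15 of 18 members were at least 2-fold higher. IL6 (Entrez gene 3569) differed by 3.31, the cyclooxygenase PTGS2 by 3.53, the monocyte chemokine CCL2 by 2.88, CCL20 by 2.69, CCL5 by 2.65 and IL1B by 2.23, and NFKBIA, the inhibitor of NF-kB, by 0.24. In limma 4 of 14 rose over all genes and 10 over the list alone. The list was also 0.68 higher in the 21-day control than in the vehicle array, CXCL8 by 3.26 and IL1B by 2.24. The matrix list had a median of 0.13 (-0.08 to 0.64, percentile 95.58) with members in both directions: LUM was at 2.54, the stromelysin MMP3 at 2.03 and the collagenase MMP1 at 1.34, while the collagens COL1A1 and COL12A1 were at -1.16 and -1.13. In limma 2 of 24 passed over all genes and 5 over the list alone, 4 higher and 1 lower. Its untreated median was 0.16. TIMP3, a metalloprotease inhibitor, was at 3.04 in this comparison, but its level of 8.37 was close to the 8.33 of the vehicle array and the 21-day control stood at 5.33. The elastase inhibitor PI3 showed the same order, with 7.37, 4.89 and 8.36 in vehicle, control and crizotinib. Other secreted factors were IGFBP3 at 3.33, the growth factor FGF7 at 3.41, the Wnt agonist RSPO3 at 3.41 and the interleukin antagonist IL36RN at 3.36.

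All 18 p53 targets were above 0, with a median of 0.61 (0.47 to 1.09, percentile 100) and 5 at least 2-fold higher. TP53INP1 was at 2.04, PHLDA3 at 1.54, the stress cytokine GDF15 at 1.25, the ribonucleotide reductase subunit RRM2B at 1.18 and the p53 ubiquitin ligase MDM2 at 1.09, and limma placed 0 of 18 past the threshold over all genes and 8 over the list alone. Hypoxia targets had a median of 0.80 (0.17 to 1.43, percentile 100), with adrenomedullin (ADM) at 1.83, NDRG1 at 1.79 and BNIP3 at 1.53, whereas VEGFA was at -0.10. Glycolysis had a median of 0.20 (-0.05 to 0.68, percentile 98.69), with the glucose transporter SLC2A1 at 1.14. Both lists were lower in the 21-day control than in the vehicle array, at -0.32 and -0.23, and the level of NDRG1 was 10.06 in vehicle, 8.66 in the control and 10.45 in crizotinib. Against the vehicle array the glycolysis median turned to -0.07.

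FOXO targets had a median of 0.67 (0.42 to 1.00, percentile 100), with CITED2 at 1.80, the superoxide dismutase SOD2 at 1.24 and TXNIP at 1.02. Lysosome genes were at 0.31 (0.17 to 0.45, percentile 100), led by cathepsin F (CTSF) at 1.97, and autophagy genes at 0.37 (0.05 to 0.63, percentile 100), with MAP1LC3B at 1.23 and WIPI1 at 1.15. Drug efflux and metabolism genes had a median of 0.30 (-0.02 to 0.50, percentile 99.67), with CYP3A5 at 1.23 and the transporter ABCB1 at 0.31 near background. Metallothioneins were at 0.32 (-0.20 to 0.79, percentile 98.98). The ERK feedback list had a median of 0.33 (-0.10 to 0.82, percentile 99.97) and members on both sides, 12 above and 8 below 0, with DUSP6 at 1.30, DUSP5 at 1.08 and CCND1 at 0.82, but FOSL1 at -0.85. Cholesterol synthesis was at 0.27 (0.01 to 0.61, percentile 99.40), with STARD4 at 1.19 and INSIG1 at 1.16 but the acetoacetyl-CoA thiolase ACAT2 at -1.16. Against the mean of the untreated arrays its median turned to -0.19, and against the vehicle array the median turned to -0.74, STARD4 to -0.74 and INSIG1 to -0.43. In limma the calls over all genes and over the list alone were 1 and 4 of 15 for hypoxia targets, 1 and 5 of 13 for FOXO targets, 1 and 1 of 30 for lysosome genes and 4 and 8 of 11 for histones, of the latter 2 higher and 6 lower. No member of the ERK feedback, cholesterol synthesis, glycolysis, autophagy, drug efflux or metallothionein list passed either way.

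Lower in the chronic comparison were NRF2 targets (-0.37, -0.65 to -0.02, percentile 0.32). Of these, SLC7A11 was among the lowest genes given above and the quinone reductase NQO1 was at -1.28, although HMOX1 was at 1.84. In limma 1 of 16 was lower over all genes, and over the list alone 2 were higher and 4 lower. Mitochondrial ribosomal proteins were at -0.44 (-0.57 to -0.31, percentile 0.0), cytosolic ribosomal proteins at -0.29 (-0.35 to -0.08, percentile 0.46), the tricarboxylic acid cycle at -0.34 (-0.46 to -0.13, percentile 0.73), with citrate synthase (CS) at -0.67, and respiratory complexes II to V at -0.21 (-0.37 to -0.09, percentile 1.96). Serine and one-carbon synthesis had a median of -0.51 (-1.06 to 0.06, percentile 0.09), with the aminotransferase PSAT1 at -1.45 and PHGDH at -1.21, and limma placed 0 of 12 past the threshold over all genes and 2 over the list alone. It placed none in the ribosomal, tricarboxylic acid and respiratory lists. The serine and one-carbon list was 0.39 higher in the 21-day control than in the vehicle array, PHGDH by 0.48 and PSAT1 by 0.37. Its chronic difference was therefore measured from a higher control. The other lists lay within the central 95%. Their medians were -0.08 for respiratory complex I, -0.10 for fatty acid oxidation, -0.16 for mitochondrial biogenesis regulators and -0.07 for fatty acid synthesis. ATF4 and amino acid response genes were at 0.13, with 5 of 25 at least 2-fold higher and 2 at least 2-fold lower. The unfolded protein response was at 0.01, heat shock genes at -0.17 and the BCL2 family at 0.13. Medians were 0.12 for receptor tyrosine kinases, 0.09 for growth factor ligands, -0.08 for YAP and TEAD targets, -0.12 for TGF-beta targets, 0.14 for interferon-stimulated genes, -0.08 for glioma stem and proneural genes and 0.11 for astrocyte and neuron differentiation. Of 28 measured receptor genes, 2 were at least 2-fold higher, PDGFRA at 1.66 and NTRK3 at 1.11, the latter below the level filter. At least 2-fold lower were 0, with AXL at -0.99. The foreign cell lists were at -0.03 (leukocyte), 0.15 (endothelial) and 0.04 (epithelial), the last with 1 of 11 members at least 2-fold higher, the claudin CLDN4 at 1.43. The epithelial transcription factor EHF, outside the lists, was at 3.52. MET differed by -0.38, HGF by -1.03, ALK by 0.15, ROS1 by -0.08, PPARGC1A by 0.46 and CREB1 by -0.09.

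In limma, 177 genes passed an adjusted p of 0.05 in the chronic comparison, 42 higher and 135 lower, and the smallest adjusted p was 0.0241. With trend and robust settings 336 genes passed. H2BC14 fell by 4.39 (SE 0.23) and the interleukin antagonist IL1RN rose by 3.10 (SE 0.23), both with adjusted p = 0.0241 in limma. Without the level filter 0 genes passed, with a smallest adjusted p of 0.0559 in limma and 2952 features at an unadjusted p of 0.05. Against the 24-hour vehicle array, 329 of the 494 higher and 372 of the 508 lower genes were again at least 2-fold apart in the same direction, and many of the highest genes, such as SERPINB4, DCN and MMP12, lay below the level filter in the control, so that their fold sizes are inexact.

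**Figure D2:**
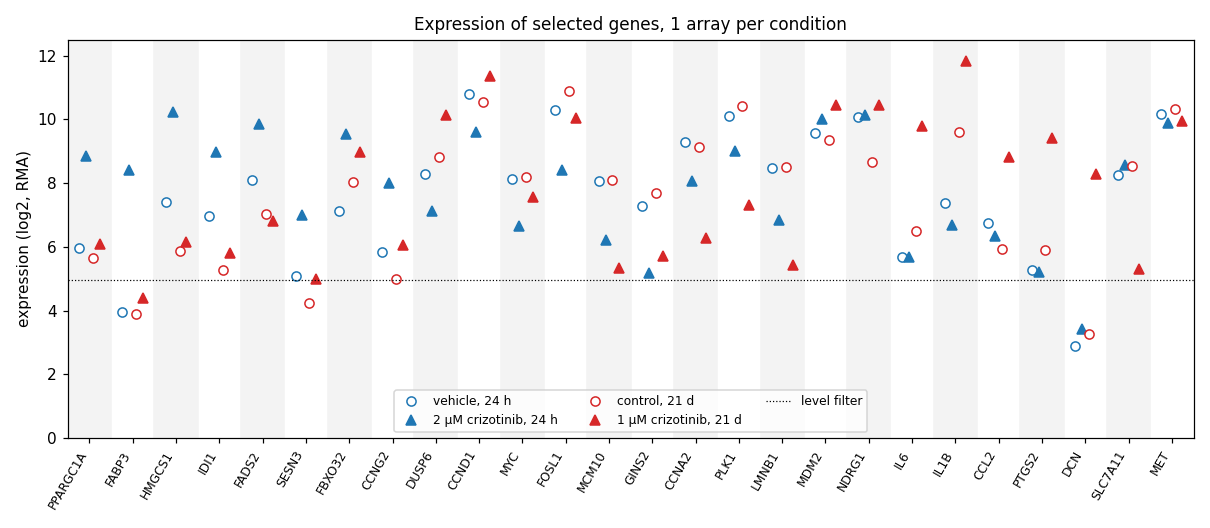
Log2 expression of selected genes on each of the 4 arrays, with open circles for arrays without drug, triangles for crizotinib, blue for the 24-hour and red for the 21-day pair; the dotted line is the level filter at 4.96. PPARGC1A stands at 8.85 after 24 hours of crizotinib and at 5.97, 5.64 and 6.10 on the other arrays, while PLK1 stands at 7.30 after 21 days and between 9.01 and 10.41 elsewhere.

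The arrays without drug came from separate cultures and differed too, which gives a yardstick for both comparisons. Of 12397 features that passed the filter, 379 were at least 2-fold apart, 208 higher and 171 lower in the 21-day control, or 3.06%, against 5.00% in the acute and 8.05% in the chronic comparison. The collagenase MMP1 was 5.02 higher in the 21-day control, CXCL8 3.26 and the hyaluronan synthase HAS2 3.12, while the repressor E2F7 was at -4.36 and the netrin receptor DCC at -3.31. Lists outside the central 95% of random lists numbered 11 of 39, against 19 in the acute and 20 in the chronic comparison. Members that vary independently would give 1.95 such lists. Genes of a list may move together, so 1.95 is no chance level for these arrays. Besides those given with the treated comparisons, ATF4 and amino acid response genes had an untreated median of 0.24 and astrocyte and neuron differentiation genes -0.27. Receptor ROS1 was 2.14 higher in the 21-day control.

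All measured replication genes and most histone genes were lower in both comparisons, and a smaller set of genes was higher in both. Among 11873 features that passed the filter in both, 79 were at least 2-fold higher and 133 at least 2-fold lower in both, where independent lists of these sizes would share 9.3 and 10.5. Of the acute lower genes 52.0% were also lower in the chronic comparison, while 3 were at least 2-fold higher there. Of the acute higher genes 27.9% were also higher, and 7 were at least 2-fold lower. Lower in both were the histone genes H2AC4, at -2.45 and -2.40, and H1-5, at -2.20 and -3.60, and the helicase subunit GINS2, at -2.12 and -1.99. Higher in both were the secreted glycoprotein CHI3L1 at 2.14 and 3.19, ATP6V0D2 at 2.48 and 1.75, the peptidase DPP4 at 1.74 and 1.72, the interferon-induced GTPase MX2 at 1.77 and 1.76, the actin capping protein TMOD1 at 1.69 and 1.85 and CREBRF, a regulator of CREB3 family factors, at 1.66 and 1.66. Across genes, which are not independent replicates, the acute and chronic differences correlated with r = 0.435 and rho = 0.364. No array is shared between these comparisons, so simulated arrays with independent noise and without effect gave r = 0.007 by construction. That simulation holds no variation that genes share, so it cannot tell what the measured r reflects. With the untreated arrays exchanged r turned to -0.063, and against their mean it was 0.313, where simulated arrays without effect gave 0.34.

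Among genes that passed the level filter in both comparisons, chronic minus acute was highest for IGFBP1 at 3.74, PTGS2 at 3.60, IGFBP3 at 3.49, IL6 at 3.32, CCL2 at 3.31 and PI3 at 2.96. It was lowest for the kinase CDK15 at -4.03, SLC7A11 at -3.58, ACAT2 at -2.87, TMEM119 at -2.56, DLGAP5 at -2.54 and HMGCS1 at -2.52. Genes that passed it in only 1 comparison are left out here, such as SERPINB4 at 5.56 and FABP3 at -3.97. These differences were not tested, and dose and time both differ between the pairs. A limma fit of crizotinib over both pairs, which takes the difference between the pairs as its spread, gave 0 genes at an adjusted p of 0.05 and 1737 at an unadjusted p of 0.05, with a smallest adjusted p of 0.153. Adjusted over the list alone, it placed 33 of 34 DNA replication genes, 32 of 33 G2/M genes and 6 of 11 histones lower and 8 of 13 FOXO targets and 5 of 19 cholesterol synthesis genes higher.

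**Figure D3:**
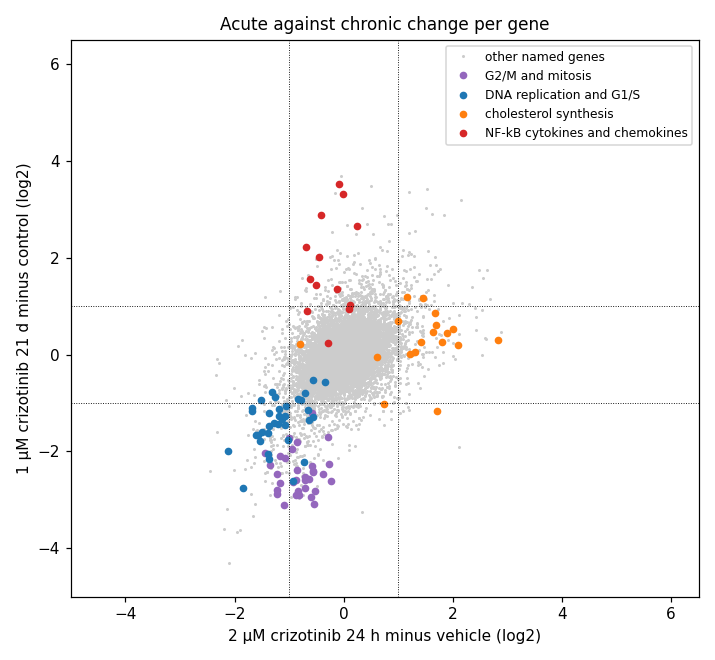
Log2 difference per gene after 21 days of 1 µM crizotinib (vertical axis) against that after 24 hours of 2 µM (horizontal axis), for named genes that pass the level filter in both comparisons, with dotted lines at 2-fold. Mitotic and replication genes lie in the lower left quadrant, cholesterol synthesis genes to the right except PMVK at -0.80 (median 1.45 acute, 0.27 chronic) and most NF-kB cytokines at the top (median 1.90 chronic); the medians are over all measured members.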

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

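The tests of array noise and of a low vehicle array were chosen after the results were seen. A few lists and genes moved in opposite directions in the acute and chronic comparisons; with 1 array per condition none of these differences was tested, and dose, time and experiment differ together.

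The NRF2 target list was higher after 24 hours and lower after 21 days, with a difference of medians of -0.59, and the ERK feedback list went the other way, with 0.81. Among genes, DUSP6 differed by 2.46 between the comparisons, ACAT2 by -2.87, the aldo-keto reductase AKR1B10 by -2.25, ID3 by -2.33 and CDK15 by -4.03. For CDK15 both directions turn when the untreated arrays are exchanged, since its level was 2.90 in the vehicle array and 5.56 in the 21-day control. ID3 depends on the control as well. Its level was 6.54 in vehicle, 7.73 in 24-hour crizotinib, 7.56 in the 21-day control and 6.41 in 21-day crizotinib. Each crizotinib array thus lay near the untreated array of the other experiment.

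The first pattern weighed is the difference between the 24-hour and the 21-day experiment. If array noise in the untreated arrays were its source, genes 2-fold apart between them would differ with either sign equally often between the treated arrays. Of 379 such genes, 339 (89.4%) had the same sign there, and 211 were at least 2-fold apart the same way, which argues against array noise. The test covers only noise that is independent between arrays. A difference between the cultures, by passage, density or stock, may remain, and so may a technical difference shared by the arrays of a pair. The design gives no group that tests either.

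The second pattern is the higher cholesterol synthesis in the acute comparison. If a low vehicle array were the cause, that array would lie below the 21-day control. It did so for 1 of 19 members (5.3%), but this list stood apart between the untreated arrays, at -0.83, so the 21-day control is no sure reference. A low vehicle array relative to its own experiment therefore stays open, and an effect of the drug may account for the pattern as well, untested without a repeat.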

How the results depend on the processing

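The control from the other experiment was chosen as an alternative after seeing that the untreated arrays differ; the other settings were planned, except quantile normalization for lists. Quantile normalization and centring left all size counts within 1.5 times, with correlations of 0.433 and 0.435. No named gene or list was counted as moved or turned under them. Little movement was possible by construction, since RMA already normalizes by quantiles. The medians of all differences were -0.01 (acute), 0.01 (chronic) and 0.003 (untreated) before centring. The share of higher calls moved by no more than 10 points under any setting. With a filter at the 75th percentile of values there were 178 acute higher, 268 chronic higher and 326 chronic lower genes, 152 untreated and 132 shared; fewer genes enter by construction. At 1.5-fold these were 1269 acute higher and 1091 lower, 1337 chronic higher and 1398 lower, 1427 untreated and 828 shared. The correlation was 0.318 without the filter, 0.51 at the 75th percentile and 0.313 against the mean of the untreated arrays, where simulated arrays without effect give 0.34 through the shared control; the covariance there was 0.103 against 0.047 simulated. Against the untreated array of the other experiment it was -0.063, since the difference between experiments then enters the comparisons with opposite signs, and acute calls rose to 681 higher and 656 lower. In limma the acute and the chronic count were both 0 without the level filter, and the chronic count was 336 with trend and robust settings; the cause was not tested. The chronic cholesterol synthesis median turned to -0.19 against the mean and -0.74 against the other untreated array, and chronic glycolysis to -0.072. Against that array, chronic differences became -0.019 for SPRY1, -0.74 for STARD4, -0.19 for ALDOC, -0.43 for INSIG1, -0.14 for NTRK3 and 0.74 for CDK15, and acute ones -0.57 for ABCC2, -0.021 for CYP1B1 and -0.54 for CDK15. There, 313 of 808 gene values and 17 of 78 list values were counted as moved, and against the mean 140 and 3. For lists, a turn was counted only outside the central 95%, so values counted as moved can also have changed sign. For ROS1 the acute difference was 0.39, yet its level was 5.04 after 24 hours of crizotinib and 6.79 in the 21-day control. Unmatched random lists left all 78 list comparisons on the same side of the central 95%. With lists limited to members past the filter, 2 list values moved, both of astrocyte and neuron differentiation, and 75 did not. Averaging several features per gene did not apply. The fit over both pairs gave 0 genes with and without the pair term. Signal near background limits fold sizes of genes below the level filter on 1 array.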

Other observations

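The test of variation between cultures was chosen after its result was seen. The experiments also differed in genes outside the lists. The actin bundling protein LCP1 was 2.73 higher in the 21-day control than in the vehicle array and the matrix glycoprotein EMILIN2 2.78, and between the crizotinib arrays these differences were 2.13 and 3.04. The endothelial-type proteoglycan ESM1 was 2.72 higher (2.98 between the crizotinib arrays), while the plasma glycoprotein APOH was at -3.73 (-3.50) and the cancer-testis gene CT45A5 at -3.98 (-4.81). The matrix protein EFEMP1 was at -3.06 between untreated arrays and also 2.01 higher after acute crizotinib. Interferon-stimulated genes at least 2-fold changed went both ways: IFIT1 was at 1.86 and MX2 at 1.77 in the acute comparison, and MX2 at 1.76, OAS2 at 1.17, IFI44 at -1.24 and IFI44L at -2.14 in the chronic one.

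The last pattern weighed is the higher level of NF-kB cytokines and of single genes such as SERPINB4 and DCN in the 21-day crizotinib array. Keratinocyte RNA was considered because SERPINB4, PI3, IL36RN, EHF (3.52) and CLDN4 (1.43) are epithelial genes. PI3 already stood at 7.37 in vehicle and 7.88 after 24 hours of crizotinib, near its 8.36 in the 21-day crizotinib array. IL36RN rose from 4.64 in vehicle to 5.83 after 24 hours of crizotinib. A high level of PI3 and a rise of IL36RN were thus also seen outside the 21-day drug culture. SERPINB4, EHF and CLDN4 differed by only 0.37, 0.16 and 0.23 in the acute comparison. Of 14 low keratinocyte markers, 0 (0.0%, exact 95% interval up to 23.2%) were 2-fold higher, and KRT5 and KRT14 stayed at 3.15 and 2.84. These markers argue against keratinocytes but do not cover other epithelial cells. Fibroblast RNA is undecided. Of 9 low fibroblast markers, 2 (22.2%, exact 95% interval 2.8 to 60%) were 2-fold higher, PDGFRA and MFAP5. MFAP5 rose only to 4.54, below the level filter. LUM reached 8.67 but was also 1.30 higher after 24 hours of crizotinib in the other experiment. COL3A1 stayed at 4.28 and COL1A1 was at -1.16, and U87 cells themselves express collagens. Variation between cultures without drug is also undecided, as 6 of 18 NF-kB list members (33.3%) moved further between the untreated arrays. A candidate explanation is a secretory programme of arrested cells: 22 further secreted factors had a chronic median of 0.32 (95% binomial interval -0.02 to 0.77), above 99.95% of random lists, with CXCL5 at 2.56, IGFBP4 at 2.16 and STC1 at 1.06 (named after their values were seen), but the interval includes 0, only 8 were at least 1.5-fold higher and fibroblast RNA could raise the same genes.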
